A study of Trametes versicolor with 17 samples.

How the data were processed

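RNA was measured in mycelial pellets of the white-rot fungus Trametes versicolor (1 strain label for all samples). Per the labels' protocols, the pellets grew at 28 °C and 135 rpm in 2% malt extract medium, with or without 5% of an aqueous phase from hydrothermal liquefaction, the process that turns wet waste into an oil under heat and pressure and leaves a water fraction rich in dissolved organics. The feedstock was food waste for the phase called FW, waste of salad dressing for the one called SD, and biomass of algae for the one called AB. RNA was taken after 3 days (72 h) in a batch the labels call main and after 7 days in a batch they call preliminary. Per the labels' protocols, RNA was extracted with TRIzol and a plant RNA column kit, and polyA-selected libraries were made from 200 ng of total RNA.

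The deposited values are whole-number read counts per gene model, not normalised. HISAT2 and featureCounts are the tools named, per the submitters' processing notes. Their versions, the genome build, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Of 280 gene models that overlap another model, the strand setting bears on the 158 that overlap one on the opposite strand. Reads from near-identical gene copies could be shared between members of a family such as the manganese peroxidases, and their values are uncertain to that extent. No read-level data and no genome sequence were used here.

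The count tables hold 14296 gene models on 236 scaffolds, with the coordinates that are printed here. The models were named by an exact match of start and end to the RefSeq gene table of assembly Trametes versicolor v1.0. Of the 14296 models 14214 matched, and 42 of them carry a gene symbol. The reference table gives locus tags and symbols without product descriptions. Of the 34 gene lists planned on product descriptions only 2 could be formed, from symbols: laccases and multicopper oxidases (8 genes) and heme peroxidases (31 genes). The latter list took the symbols LiP, MnP, VP, DyP and HTP and left out CCP1. Subfamilies by symbol (MnP, LiP, TvLac) were added after seeing the data. No list of markers of RNA quality or growth state could be formed.

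Comparisons of the 4 groups at 3 days came from 1 model over 12 libraries, the 7-day comparison from the 5 preliminary libraries, and the difference between the AB responses at 7 and 3 days from 1 model over all 17 libraries. Each used edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default filter on low counts by group, and the quasi-likelihood F test, two-sided. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p of 0.05. The filter left 10838, 10192 and 11057 genes. The biological coefficient of variation was 0.188 in the main batch, 0.455 in the preliminary batch and 0.288 over both. Residual degrees of freedom were 8, 3 and 11. Every adjusted p of a gene printed here is from edgeR's quasi-likelihood test with that adjustment. Each SE of a log2 fold change was back-computed as its absolute value divided by the square root of the F statistic. It is approximate, above all for genes with few counts in a group. The titles call the samples biological replicates, and p-values measure the spread between them, pooled over the groups of a model.

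Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. A gene counted as responding to all 3 aqueous phases when called in the same direction in each against control. It counted as distinct to 1 phase when called against control and against both other phases in the same direction. Levels are CPM on TMM-scaled library sizes, as mean ± SD.

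Before the data were examined, the design, the lists, the alternatives and the rule for named genes were fixed. The rule took called genes with a mean of at least 10 CPM whose libraries did not overlap between the groups: the 8 largest rises and falls among genes with informative names, here those with a symbol, the 2 largest rises and falls of any gene, and 2 members of each list that passed its test. For the time difference the condition on overlap was dropped. Members of the lists and neighbouring genes named beyond this rule were chosen after their values were seen, as were the unnamed genes of the set shared by all phases. The alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter at 10 CPM, a 2-fold minimum, leaving out each library, a replicate block, fits of the compared groups alone and the estimated correlation. Thinning all libraries to the total of the smallest was added after seeing the data.

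Total counts were 15.5 to 18.8 M (1e6) per main library, where 3 counts correspond to at most 0.194 CPM, and 27.7 to 35.2 M per preliminary library. A gene without counts in a group was set to a floor of 3 counts per library, and ratios over 1 to 3 counts carry an exact 95% interval. Reads were not counted by molecular identifiers, and intervals and floors cover counting error only. On data simulated from the control means and the real depths, with 50 genes changed at each size, the AB comparison at 3 days recovered 52% of 2-fold and 88% of 4-fold changes among 10838 genes. The 7-day comparison recovered 0% and 10% among 10192 genes, and the time difference 4% and 50% among 11057 genes. For the time difference the simulated libraries of both batches started from the 3-day control means. In the data 6172 of 11057 genes were called between the 7-day and 3-day controls, so those shares describe a simpler setting. The simulations called 131, 29 and 72 genes, of which 6, 3 and 7 were unchanged genes, against 6759, 334 and 3089 calls in the data. With fewer changed genes the adjustment is stricter, so these shares may understate recovery in the real comparisons. Replicates of a group differed by more than sampling noise in all 16 pairs, and none were merged. The chi-square per degree of freedom was 12.5 to 95.8 in the main batch and 163 to 965 in the deeper preliminary batch. There AB replicate 2 differed from AB replicates 1 and 3 at 833 and 965, and the 2 controls from each other at 614.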

Results

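The data comprised 17 mRNA libraries of Trametes versicolor mycelial pellets in 6 groups. The main batch held 3 libraries each of control pellets and of pellets exposed for 3 days to 5% aqueous phase from food waste (FW), salad dressing waste (SD) or algal biomass waste (AB). The preliminary batch held 3 libraries of pellets exposed to AB for 7 days and 2 controls. Between 11501 and 11629 gene models had counts in the main libraries and between 11109 and 11359 in the preliminary ones. The 10 most abundant genes took 7.30% to 9.06% of the counts of a main library and 14.4% to 20.1% of a preliminary one. The mean scaling factor of the SD libraries was 1.10 (SD 0.0229), against 0.970, 0.973 and 0.968 in the control, FW and AB libraries at 3 days. The 7-day controls had factors of 1.24 and 0.861.

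The 4 groups at 3 days separated on the principal components. The first component held 62.9% of the variance and ran from control over SD and FW to AB, which lay farthest apart. The next held 16.9% and ran from control over SD to FW.

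**Figure D1:**
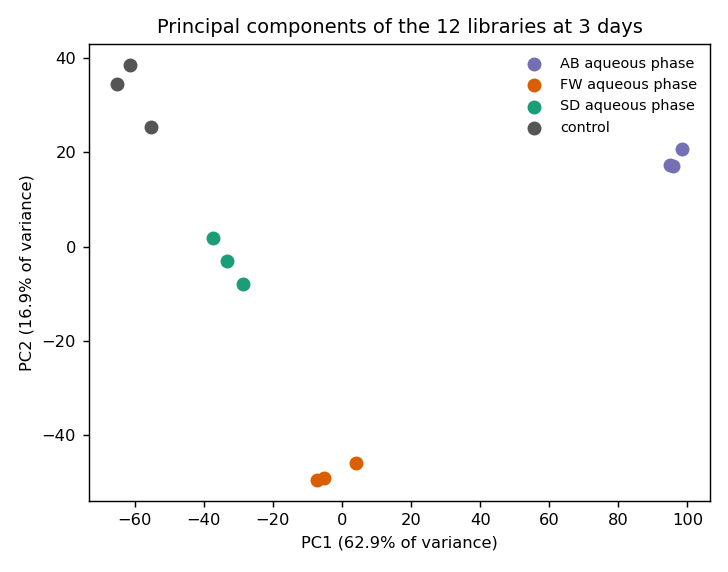
Principal components of log CPM in the 12 libraries at 3 days, 1 point per library and 3 per group. PC1 holds 62.9% and PC2 16.9% of the variance, and the libraries of each group lie together.

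Exposure to FW was compared with control to find the genes that respond to this feedstock. Manganese peroxidases (MnP), secreted enzymes that oxidise Mn(II) in the breakdown of lignin, rose in 8 of 11 tested genes. MnP13 (TRAVEDRAFT_51442; scaffold 10, 2258153 to 2258981, 3 exons) rose from 0.356 ± 0.254 to 40.0 ± 21.6 CPM (SD, n = 3), a log2 fold change of 6.78 (SE 0.62, adjusted p = 3.22e-06). Its model is short, at 714 bases, where the other MnP models have 1086 to 1215. MnP3s rose from 36.3 ± 34.5 to 629 ± 448 CPM (log2 fold change 4.11, SE 0.67, adjusted p = 0.000315) and MnP4s from 13.7 ± 3.19 to 89.3 ± 22.2 CPM (2.71, SE 0.22, adjusted p = 1.51e-06). The versatile peroxidase VP2, of a class that oxidises Mn(II) as well as aromatic substrates, rose from 1038 ± 271 to 2772 ± 1380 CPM (1.42, SE 0.32, adjusted p = 0.00292), although FW replicate 2 (1217 CPM) lay within the control range of 746 to 1281 CPM. TvLac7, a laccase (a copper enzyme that oxidises phenols), fell from 257 ± 98.9 to 75.8 ± 14.7 CPM (log2 fold change -1.76, SE 0.31, adjusted p = 0.000494).

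MnP7s, MnP5s, MnP1s, MnP9s and MnP8s also rose under FW, by log2 fold changes of 3.39, 2.58, 2.19, 1.63 and 0.91. Among the lignin peroxidases (LiP), which oxidise non-phenolic lignin units, LiP2 (2.66), LiP9 (1.26) and LiP6 (0.75) rose, LiP8 (-1.11) and LiP12 (-0.71) fell, and 5 of 10 were not called. LiP12 overlaps another gene model. Levels in the controls were low for LiP9, LiP6, LiP8 and LiP12, at 1.45, 3.77, 3.21 and 6.20 CPM. They were also low for MnP9s, MnP5s, MnP7s and MnP1s, at 0.407, 2.44, 5.12 and 5.24 CPM. Of the heme-thiolate and dye-decolorising peroxidases, HTP2 rose by 0.86, DyP2 rose by 2.35, with overlap between its FW and control libraries, and DyP1 fell by 0.58 on the log2 scale (adjusted p = 0.0312). LDO1 (scaffold 1, 623274 to 628182) fell from 5007 ± 1121 to 2749 ± 507 CPM (log2 fold change -0.87, adjusted p = 0.00392). The heme peroxidase list had 14 of 29 tested genes higher, 3 lower and 12 not called, with the same counts when adjusted over the list alone, and moved up against all other genes (camera adjusted p = 0.0252). That adjusted p was 0.131 with an estimated correlation, and 0.0531 and 0.0533 at the preset correlation without control replicate 1 or 2. The MnP subfamily had a camera adjusted p of 0.000666, and an adjusted p of 0.111 with an estimated correlation. For the LiP subfamily the adjusted p was 0.981. In the laccase list 1 of 8 genes fell and none rose (adjusted p = 0.365).

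Of the genes without a symbol, TRAVEDRAFT_128509 (scaffold 8, 422658 to 424546) rose from 25.2 ± 12.7 to 1910 ± 379 CPM (log2 fold change 6.25, SE 0.59, adjusted p = 4.62e-06). TRAVEDRAFT_33676 (scaffold 1, 3704440 to 3706138) fell from 45.6 ± 6.46 to 1.46 ± 0.152 CPM (-4.95, SE 0.33, adjusted p = 3.66e-07), and TRAVEDRAFT_47941 (scaffold 6, 2125333 to 2125812) from 52 ± 27.2 to 1.68 ± 0.755 CPM (-4.94, SE 0.48). In all, 4963 of 10838 genes were called, 2432 higher and 2531 lower, with 2220 of them at least 2-fold. The LiP2 call rested on FW replicate 1, and without it the log2 fold change was 1.79 (adjusted p = 0.0634). The DyP1 call was lost when any 1 of 4 libraries, control replicate 1 or 3 or FW replicate 1 or 2, was left out (adjusted p 0.0672 to 0.167).

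Of the MnP genes 7 lie within 93.5 kb of scaffold 10 (2217215 to 2310731), among 32 gene models. The 6 that were tested had a median log2 fold change of 3.05 under FW (range 0.91 to 6.78), against 0.10 for the 22 other tested genes of the region, of which 3 rose and 5 fell.

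**Figure D2:**
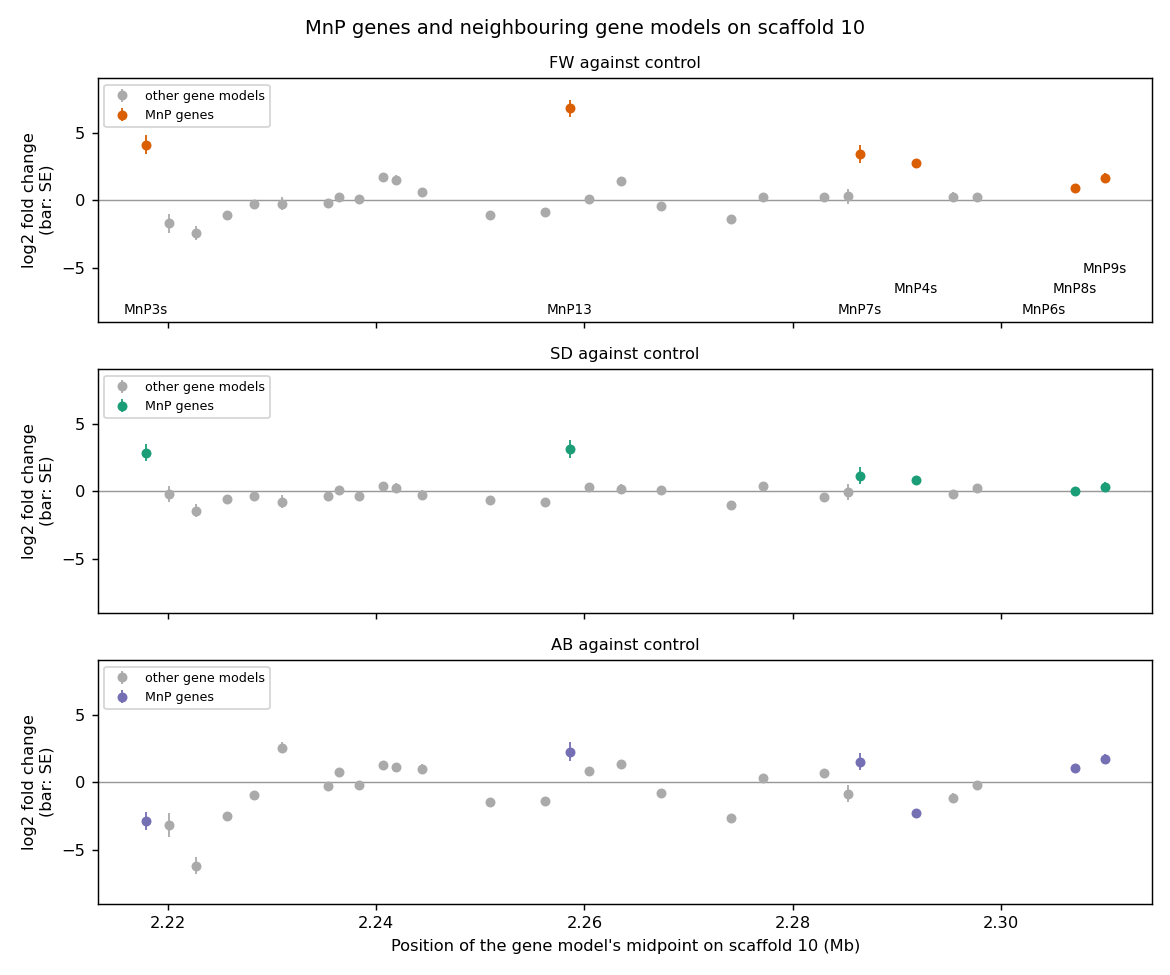
Log2 fold change with its SE (vertical axis) of tested gene models against their position on scaffold 10 in Mb (horizontal axis), under FW, SD and AB against control, n = 3 libraries per group. The 6 tested MnP genes (coloured; MnP6s is marked but was not tested) were all higher under FW, with a range of 0.91 to 6.78, while the median of the other 22 genes (grey) was 0.10.

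Exposure to SD was compared with control in the same way. TvLac7 (scaffold 6, 160728 to 162937) fell from 257 ± 98.9 to 9.70 ± 4.18 CPM (SD, n = 3), a log2 fold change of -4.72 (SE 0.35, adjusted p = 9.04e-06). MnP3s rose to 262 ± 67.9 CPM (2.85, SE 0.64, adjusted p = 0.00764), and MnP13 (3.10), MnP5s (2.71) and MnP4s (0.79) rose too, 4 of 11 tested MnP genes. LiP2 rose from 7.29 ± 1.48 to 87.2 ± 104 CPM (3.58, SE 0.78, adjusted p = 0.00653), a mean with an SD larger than itself, and LiP9 rose by 1.04. LDO1 fell from 5007 ± 1121 to 1826 ± 405 CPM (-1.46, SE 0.21, adjusted p = 0.000565). CCP1, whose symbol stands for cytochrome c peroxidase, an enzyme that detoxifies hydrogen peroxide in mitochondria, fell from 168 ± 50.5 to 77.0 ± 19.9 CPM (-1.13, SE 0.26, adjusted p = 0.00882).

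The heme-thiolate peroxidases moved apart under SD. HTP3 fell from 1807 ± 85.4 to 1011 ± 312 CPM (log2 fold change -0.84, adjusted p = 0.00844), while HTP1 (1.15, adjusted p = 0.0438) and HTP2 (0.67, adjusted p = 0.0353) rose. DyP1 fell by 0.87 and LDO2 by 0.55 on the log2 scale. The heme peroxidase list had 8 of 29 genes higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.0918, and 0.0283 without control replicate 3). The laccase list moved down (adjusted p = 0.0245) although only TvLac7 of its 8 genes was called, also when adjusted over the list alone. That adjusted p was 0.235 with an estimated correlation, 0.159 without control replicate 2 and 0.0803 without SD replicate 1. The MnP subfamily had an adjusted p of 0.0305, and an adjusted p of 0.315 with an estimated correlation, and for LiP the adjusted p was 0.499.

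Of the genes without a symbol, TRAVEDRAFT_60089 (scaffold 9, 2095074 to 2095973) rose from 0.549 ± 0.312 to 20.1 ± 3.45 CPM under SD (log2 fold change 5.20, SE 0.33, adjusted p = 4.08e-06) and TRAVEDRAFT_122207 (scaffold 5, 786751 to 788996) from 3.49 ± 1.13 to 74.9 ± 11.8 CPM (4.43, SE 0.31). TRAVEDRAFT_51581 (scaffold 11, 118611 to 119330) fell from 27.4 ± 9.87 to 1.73 ± 0.549 CPM (-3.98, SE 0.39). In all, 2291 genes were called, 1111 higher and 1180 lower, with 819 at least 2-fold, and 1361 were called without control replicate 3. The calls of HTP1, HTP2, MnP4s and LDO2 were each lost without 1 of several libraries, with adjusted p-values up to 0.188, 0.139, 0.0639 and 0.113.

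Under AB, VP2, HTP3 and LDO1, which were abundant in the controls, fell. VP2 (scaffold 2, 411397 to 413494) fell from 1038 ± 271 to 3.39 ± 0.235 CPM (SD, n = 3), a log2 fold change of -8.26 (SE 0.44, adjusted p = 8.42e-09). HTP3 fell from 1807 ± 85.4 to 36.1 ± 2.26 CPM (-5.64, SE 0.23, adjusted p = 7.72e-10), LDO1 from 5007 ± 1121 to 229 ± 14.7 CPM (-4.45, SE 0.23), and TvLac7 from 257 ± 98.9 to 1.82 ± 0.577 CPM (-7.13, SE 0.41). The opposite held for MnP1s, which rose from 5.24 ± 0.989 to 176 ± 102 CPM (5.07, SE 0.41, adjusted p = 2.97e-07), and MnP10s (scaffold 3, 2713545 to 2714883), which rose from 15 ± 4.86 to 389 ± 250 CPM (4.70, SE 0.44, adjusted p = 1.04e-06).

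The MnP subfamily went both ways under AB, with 5 of 11 tested genes higher and 3 lower (camera adjusted p = 0.554), and 6 higher with RLE size factors. MnP13 (2.26), MnP9s (1.71) and MnP8s (1.02) also rose, and MnP11s (-4.0), MnP3s (-2.86) and MnP4s (-2.26) fell. All 3 versatile peroxidases fell, with log2 fold changes of -8.26, -4.52 and -1.91 for VP2, VP3at and VP1, as did DyP2 (-6.55), DyP1 (-3.36), HTP2 (-3.27) and LDO2 (-4.83). VP1 was scarce, at 1.55 ± 0.547 CPM in the controls and 0.403 ± 0.400 CPM under AB. Of the LiP genes LiP6 rose by 1.06, while LiP8 (-1.80), LiP1 (-1.11) and LiP4 (-1.10) fell (subfamily adjusted p = 0.623). Levels in the controls were low for LiP8, LiP1, LiP4 and LiP6, at 3.21, 2.26, 1.55 and 3.77 CPM, and for MnP9s and MnP13, at 0.407 and 0.356 CPM. The heme peroxidase list had 6 of 29 genes higher and 13 lower, or 7 and 15 when adjusted over the list alone, and 7 higher with RLE size factors. Its camera adjusted p was 0.0605, 0.196 with an estimated correlation, and 0.00654 to 0.0447 in 6 other alternatives. In the laccase list TvLac7, TvLac5 (-2.12), TvFet3A (-1.77) and TvLac6 (-0.52) fell and none rose, 4 of 8 also when adjusted over the list alone (camera adjusted p = 0.117).

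TRAVEDRAFT_174721 (scaffold 13, 603124 to 605868), at 4325 ± 1370 CPM among the abundant transcripts of the controls, fell to 3.37 ± 0.326 CPM under AB (log2 fold change -10.32, SE 0.36, adjusted p = 3.44e-10). TRAVEDRAFT_42584 (scaffold 1, 4479612 to 4481092) fell from 751 ± 198 to 0.721 ± 0.412 CPM (-10.02, SE 0.38). TRAVEDRAFT_51486 (scaffold 10, 2414909 to 2415317) rose from 0.133 ± 0.123 to 141 ± 33.7 CPM (9.92, SE 0.37, adjusted p = 4.20e-10). TRAVEDRAFT_54052 (scaffold 15, 575685 to 576430) had 2 counts in the controls and reached 27.2 ± 11.4 CPM, a ratio of 716 with a counting interval of 198 to 5912. In all, 6759 of 10838 genes were called, 3228 higher and 3531 lower, with 3854 at least 2-fold. The MnP13 call was lost without control replicate 1 (adjusted p = 0.0536).

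**Figure D3:**
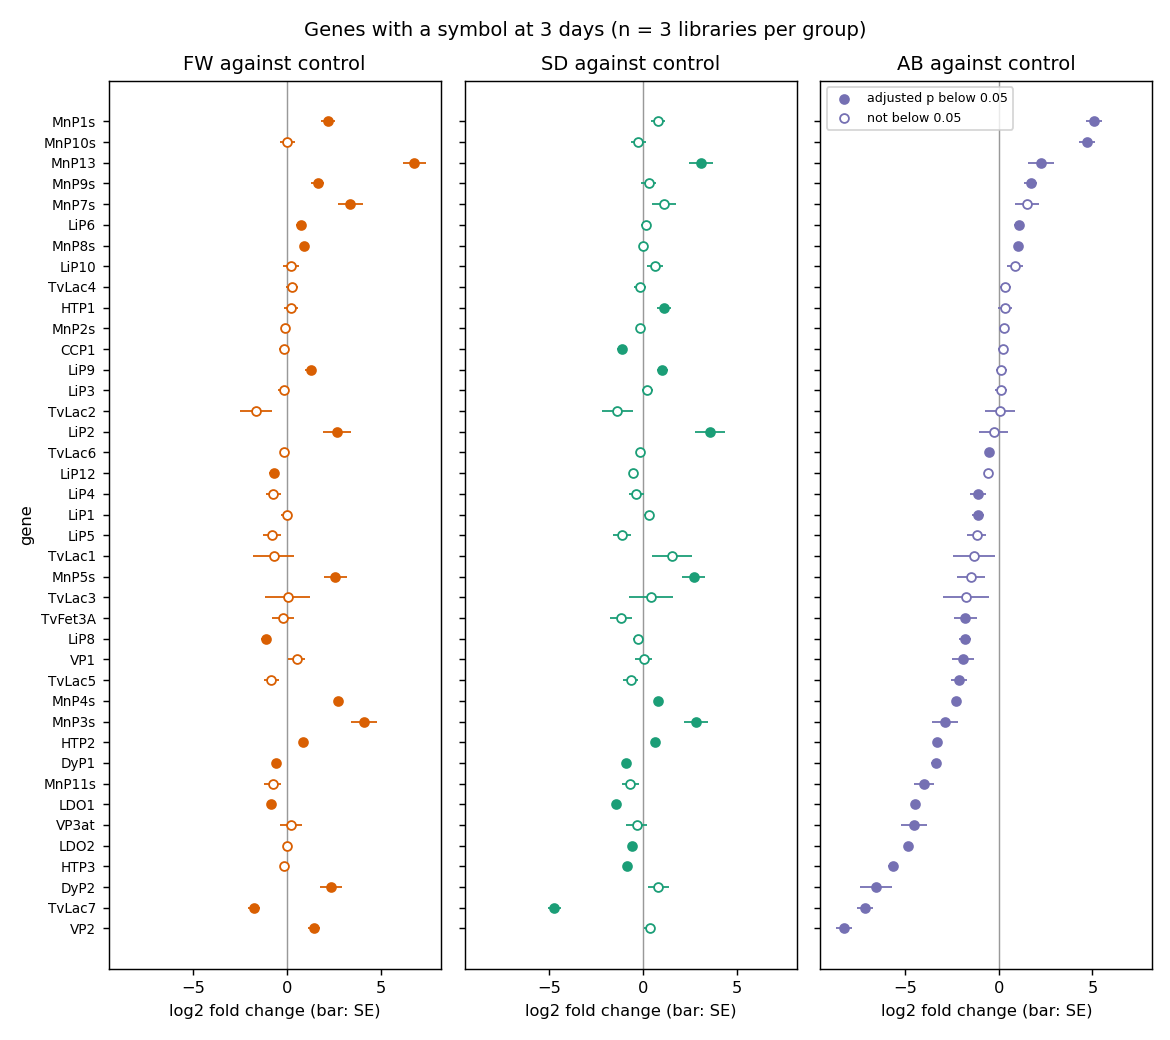
Log2 fold change against control (horizontal axes, bars are SE) of the 40 tested genes with a symbol under FW, SD and AB at 3 days, n = 3 libraries per group, with filled points at an adjusted p under 0.05. Genes are ordered by their value under AB, from 5.07 for MnP1s down to -8.26 for VP2.

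The aqueous phases were also compared with each other. Between FW and SD, MnP13 (log2 fold change 3.67, SE 0.47, adjusted p = 0.000198), TvLac7 (2.96, SE 0.33), MnP7s (2.24, SE 0.61) and MnP4s (1.91, SE 0.21) were higher under FW, and LiP8 was lower (-0.83, adjusted p = 0.0477). Against AB, VP2 was higher by 9.67 (SE 0.47) under FW and by 8.61 (SE 0.45) under SD, DyP2 by 8.89 and 7.37, MnP3s by 6.97 and 5.71, and HTP3 by 5.48 and 4.81. MnP10s was lower than under AB by log2 fold changes of -4.68 under FW and -4.94 under SD, and MnP1s by -2.87 and -4.25. MnP9s (-1.40) and CCP1 (-1.37) were lower under SD than under AB.

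The heme peroxidase list was higher under FW than under AB, with 16 of 29 genes higher and 2 lower (camera adjusted p = 3.00e-06, and an adjusted p of 0.00904 with an estimated correlation). It was also higher under SD than under AB, with 15 genes higher and 5 lower (adjusted p = 0.00180, and 0.0327 with an estimated correlation). Both pairs of counts were the same when adjusted over the list alone. Between FW and SD the list had 8 genes higher and 1 lower (adjusted p = 0.0498, and 0.187 with an estimated correlation), also when adjusted over the list alone, and 2 lower with DESeq2. That list call was also lost with RLE size factors (adjusted p = 0.0516) and without any 1 of 6 libraries (adjusted p up to 0.135). The adjusted p-values of the laccase list were 0.202, 0.118 and 0.430 for FW against SD, FW against AB and SD against AB. Between FW and SD 2757 genes were called, between FW and AB 4564, and between SD and AB 5871. The MnP7s call between FW and SD was lost without FW replicate 3 or SD replicate 1 or 3 (adjusted p 0.0558 to 0.0613), and the LiP8 call in 9 of 12 alternatives.

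The series title asks which genes respond to every feedstock. MnP13 was the only tested gene with a symbol that rose under all 3 aqueous phases, from 0.356 CPM in the controls to 40.0, 3.13 and 1.74 CPM under FW, SD and AB, with an AB call that was lost without control replicate 1 (adjusted p = 0.0536). TvLac7, LDO1 and DyP1 fell under all 3, and their log2 fold changes under FW, SD and AB were -1.76, -4.72 and -7.13 for TvLac7, -0.87, -1.46 and -4.45 for LDO1, and -0.58, -0.87 and -3.36 for DyP1, whose FW call was lost without any 1 of 4 libraries. Among genes without a symbol TRAVEDRAFT_60089 rose by 6.16, 5.20 and 4.27, and TRAVEDRAFT_51581 fell with log2 fold changes of -4.28, -3.98 and -7.52. TRAVEDRAFT_54050 (scaffold 15, 567424 to 567724) had 1 count in the controls and 64, 42 and 348 counts under FW, SD and AB, ratios of 63.3 (counting interval 11.4 to 2499), 36.6 (6.56 to 1445) and 362 (65.0 to 14308). TRAVEDRAFT_24488 (scaffold 14, 212223 to 212676) fell by 5.48 and 3.59 on the log2 scale under FW and SD, and from 230 counts to 1 under AB.

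The set held 1504 genes, 694 higher and 810 lower, where independent lists of the same sizes would share 74.3 and 89.8. Without control replicate 3 the set held 947. Unchanged groups simulated against the same controls gave 0 such genes in 20 simulations, which follows from the absence of changed genes and does not measure what shared controls add among genes that did change. Of the SD calls, 78.0% (1787) were also called in the same direction under FW and 75.4% (1728) under AB, and of the FW calls 76.0% (3774) were shared with AB. For FW and SD, 842 genes were higher in both, against 249 for independent lists, 945 lower, against 276, and 23 opposite. For FW and AB these were 1815 against 724, 1959 against 825, and 211. For SD and AB they were 791 against 331, 937 against 384, and 124. The correlation of fold changes across genes, which are not independent replicates, was 0.730 for FW and SD, 0.654 for FW and AB and 0.549 for SD and AB, where shared controls alone gave 0.512, 0.496 and 0.505. The covariances were 0.469, 1.04 and 0.566, against 0.0463, 0.0455 and 0.0460 from shared controls alone. The 3 controls could not be split into parts of at least 2 libraries, and part of the excess in shared calls may come from the shared controls.

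Genes distinct to 1 phase differed from control and from both other phases in the same direction. MnP13, MnP7s, MnP4s and VP2 were distinct to FW, all higher, and CCP1 was distinct to SD, lower. The MnP7s call between FW and SD was lost without any 1 of 3 libraries, and for VP2 FW replicate 2 overlapped with the control and SD libraries. MnP1s and MnP10s were distinct to AB as higher genes. A further 15 genes with a symbol were distinct to AB as lower genes, among them VP1, VP2 and VP3at, DyP1 and DyP2, HTP2 and HTP3, LDO1 and LDO2, TvLac5 and TvLac7. The sets held 542 genes for FW (341 higher, 201 lower), 136 for SD (86 and 50) and 3117 for AB (1494 and 1623). The FW set held 361 genes without FW replicate 1, and the SD set 82 without control replicate 3 and 90 without SD replicate 3.

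After 7 days the AB pellets (n = 3) were compared with 2 controls of the same batch. VP2 fell from 350 ± 13.8 to 5.10 ± 2.81 CPM (SD), a log2 fold change of -6.10 (SE 0.55, adjusted p = 0.0104), and VP3at from 114 ± 124 to 1.55 ± 0.606 CPM (-6.20, SE 0.92, adjusted p = 0.0273). The VP3at value was -4.06 without control replicate 1 and -7.01 without control replicate 2, with 1 control left in each. The laccases TvLac3, TvLac4 and TvLac5 fell by log2 fold changes of -3.67, -3.69 and -4.11, TvLac3 from 693 ± 205 to 54.3 ± 32.2 CPM and TvLac4 from 182 ± 125 to 14.0 ± 4.33 CPM. LDO2 fell from 55.9 ± 20.4 to 13.4 ± 3.01 CPM (-2.06, SE 0.37, adjusted p = 0.0419). The laccase list moved down, with 3 of 8 genes lower, or 4 when adjusted over the list alone and with DESeq2 (camera adjusted p = 0.000164, and 0.190 with an estimated correlation). The heme peroxidase list also moved down (adjusted p = 0.0135, 0.190 with an estimated correlation and 0.0876 without control replicate 1, with 1 control left), with 2 of 22 tested genes lower, or 3 when adjusted over the list alone, and with 3 higher and 5 lower by DESeq2. DyP2 and MnP8s, at means of 86.6 and 11.7 CPM without TMM scaling over the 12 main libraries, had 0 counts in all 5 libraries of this batch.

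TRAVEDRAFT_164045 (scaffold 3, 3166608 to 3168196) rose from 0.997 ± 0.289 to 176 ± 202 CPM at 7 days (log2 fold change 7.47, SE 1.31) and TRAVEDRAFT_53037 (scaffold 13, 414891 to 415790) from 0.510 ± 0.00126 to 79.7 ± 68.6 CPM (7.28, SE 1.25). TRAVEDRAFT_23208 (scaffold 11, 506527 to 507116) had 34.2 ± 18.9 CPM in the controls and no counts under AB, at least 356-fold lower. TRAVEDRAFT_53867, which overlaps another gene model, fell from 109 ± 96.1 to 0.116 ± 0.103 CPM (-9.90, SE 1.15). In all, 334 of 10192 genes were called, 89 higher and 245 lower (26.6% higher), while DESeq2 called 1343, 684 higher and 659 lower (50.9% higher). The edgeR fit with the replicate block called 91, 46 higher and 45 lower. In it VP3at, TvLac3, TvLac4, TvLac5 and LDO2 lost their calls (adjusted p 0.0959 to 0.213). The block leaves fewer residual degrees of freedom than the 3 of the fit without it. AB replicate 3, which has no control of its number, then takes no part in the comparison. The smaller count with the block therefore does not tell a fragile result from too few libraries. With control replicate 2 left out, 1 control remains and the spread comes from the 3 AB libraries alone, as it does with control replicate 1 left out, so these 2 fits do not tell a fragile result from too few controls. Without control replicate 2 edgeR called 0 genes (1661 at an unadjusted p of 0.05), and each 7-day gene named here lost its call, with adjusted p-values from 0.0628 for VP3at to 0.224 for TRAVEDRAFT_53037. TvLac3 and LDO2 lost their calls without any 1 of the 5 libraries (adjusted p 0.0515 to 0.192 and 0.0518 to 0.179). VP3at, TvLac5, TRAVEDRAFT_164045, TRAVEDRAFT_53037 and TRAVEDRAFT_23208 also lost theirs without control replicate 1, and VP3at and TvLac4 without AB replicate 3. The other libraries left out in turn gave 78 (control replicate 1), 208, 689 and 164 (AB replicates 1, 2 and 3).

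The AB response at 7 days differed from that at 3 days in many genes, although exposure time and batch coincide. TvLac7, LDO1 and HTP3 fell under AB at 3 days, while their 7-day controls were already low, at 0.565 ± 0.0759, 77.4 ± 33.8 and 3.68 ± 0.973 CPM (SD, n = 2) against 257, 5007 and 1807 CPM in the 3-day controls. The differences between the responses were 8.26 (SE 0.73, adjusted p = 2.89e-06), 6.81 (SE 0.79) and 6.44 (SE 0.58) on the log2 scale. TvLac4 went the other way (-4.05, SE 0.58, adjusted p = 0.000141), with 18.3 CPM in the 3-day and 182 CPM in the 7-day controls and 23.3 and 14.0 CPM under AB. In all, 3089 of 11057 genes differed, 1533 upward and 1556 downward. The model behind this count pools the spread of each gene over both batches. The biological coefficient of variation was 0.188 in the main batch and 0.455 in the preliminary batch. Its p-values may therefore understate the spread between the 7-day libraries. 54 of 7882 genes with at least 2 CPM in all 12 main libraries had no counts in any of the 5 preliminary libraries. The laccase list had 1 gene up and 2 down and the heme peroxidase list 5 up and 4 down, also when adjusted over each list alone (adjusted p = 0.683 for both), and the latter had 6 up with DESeq2.

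Of 6320 genes called at 3 days and tested at both times, 66.5% had the same sign at 7 days. Genes called at both times comprised 69 higher in both, against 27.1 for independent lists, 132 lower in both, against 75.9, and 36 opposite, against 101. VP2 and LDO2 were among those lower at both times, LDO2 with a 7-day call that was lost without any 1 of the 5 libraries.

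**Figure D4:**
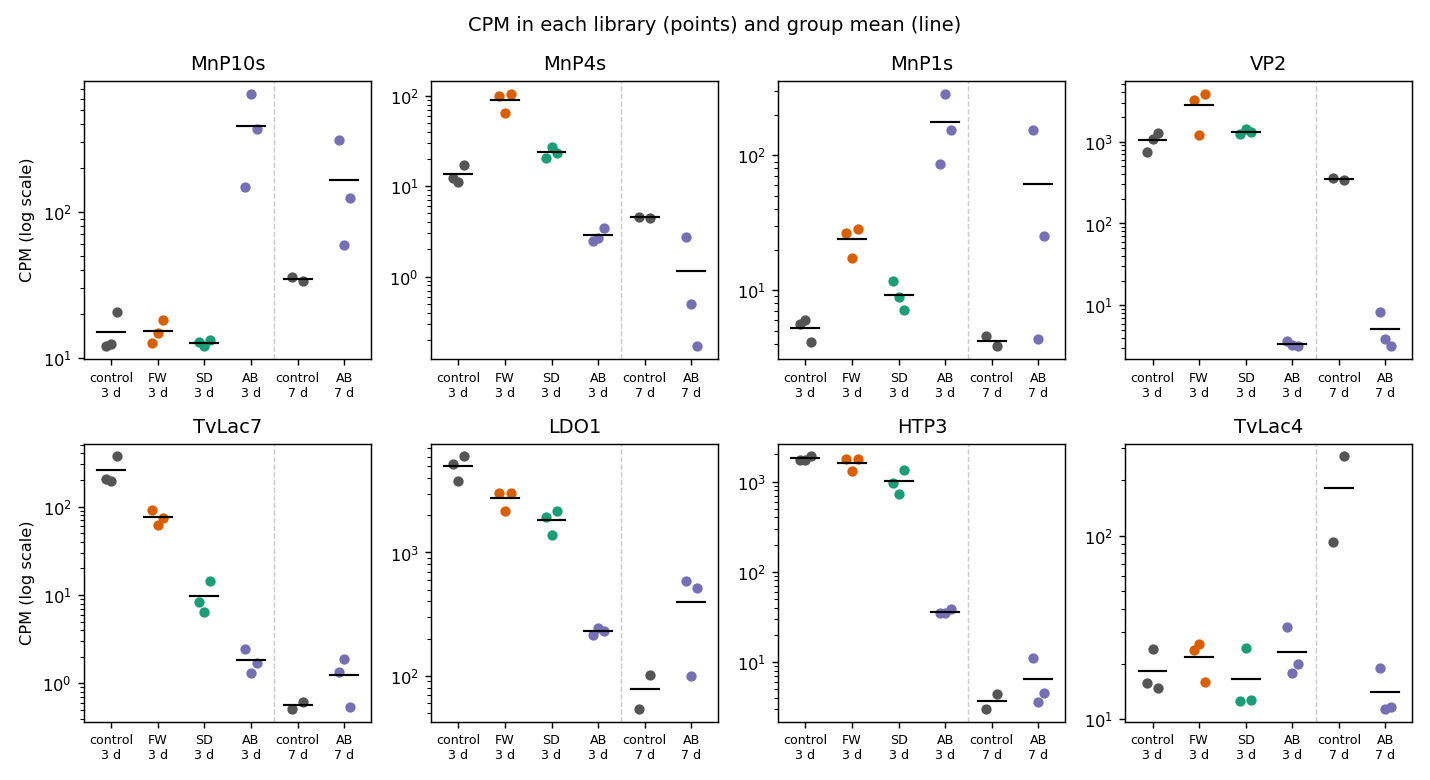
CPM on a log scale (vertical axes) in each library (points) with the group mean (line) for 8 genes in the 4 groups at 3 days and the 2 groups at 7 days. VP2 lies near 3.39 CPM under AB at 3 days and 5.10 CPM at 7 days, below its controls at 1038 and 350 CPM, while TvLac7 is at 257 CPM in the 3-day controls and at 0.565 CPM in the 7-day controls.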

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

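The tests at equal depth, on genes without counts in the preliminary batch and on reads shared between MnP copies were chosen after the results were seen; the fits without single libraries were planned, and their use as a test was chosen after their counts were seen. A test of the difference between the AB responses at 7 and 3 days picked out 3089 genes and, among the named ones, the following differences on the log2 scale (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). TvLac7 (8.26), LDO1 (6.81), HTP3 (6.44), HTP2 (5.17) and MnP11s (3.92) fell under AB at 3 days, while at 7 days their log2 fold changes of 1.14, 2.37, 0.81, 1.91 and -0.05 did not pass the test. LDO2 (2.75) and VP2 (2.14) fell at both times, with log2 fold changes of -4.83 and -8.26 at 3 days and of -2.06 and -6.10 at 7 days. The VP2 difference had an adjusted p of 0.0150, and of 0.0502 without the 7-day control replicate 2. TRAVEDRAFT_42584 was fitted at 15.73 (11.39 with the floor in the 7-day controls) and TRAVEDRAFT_52920 at 13.32 (counting interval 11.79 to 15.61). They had 0 and 3 counts in the 7-day controls and 23 and 48 in the 7-day AB libraries (0.239 ± 0.414 and 0.494 ± 0.761 CPM). The former was lost without the 7-day AB replicate 1 (9.99, adjusted p = 1.00).

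TvLac4 (-4.05) and TRAVEDRAFT_125048 (-8.58) fell at 7 days and were not called at 3 days. TRAVEDRAFT_125048 stood at only 0.411 and 0.635 CPM in the 3-day control and AB libraries, and at 67.6 ± 67.7 CPM in the 7-day controls. HTP1 (-3.18) and MnP2s (-1.86) were called at neither time alone. The MnP2s difference shrank to -0.931 without the 7-day control replicate 2, which leaves 1 control. DyP1 (-2.77) fell at 3 days, from 310 to 30.2 CPM, and stood at 66.1 ± 66.9 CPM in the 7-day controls and 0.964 ± 0.825 CPM in the 7-day AB libraries. Its difference was lost without any 1 of the 6 libraries at 3 days (adjusted p 0.0692 to 0.0785) and between the separate 7-day and 3-day results. It shrank to -0.986 without the 7-day control replicate 2, which leaves 1 control. MnP10s (-2.45) rose at 3 days, and its difference was lost without 3-day control replicate 1 or 2, 3-day AB replicate 2 or 7-day control replicate 1 (adjusted p up to 0.0751). TRAVEDRAFT_48684 (-9.46) rose from 0.107 to 36.0 CPM at 3 days and stood at 712 ± 224 CPM in the 7-day controls.

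The greater depth of the preliminary libraries does not account for the number of these differences, since 2969 genes were found at equal depth, and neither does a single library, since the lowest count without any 1 library was 2527, while single genes depend on 1 library as given above. The model behind this number pools the spread over both batches, which may make the number too large. In 68.9% of the 3089 genes the controls of the batches differed by more than the AB libraries did, with median absolute log2 differences of 1.52 and 0.78. A difference between the batches in strain, gene content or read processing stays open: 54 of 7882 genes with at least 2 CPM in all 12 main libraries had 0 counts in all 5 preliminary ones, against 11 genes with 1 to 3 counts, and none of 7056 genes went the other way. Genes that are silent at 7 days would give the same zeros. Exposure time, batch and any difference in strain or processing cannot be told apart, because each time was measured in 1 batch only.

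Of the genes without counts in the preliminary batch, TRAVEDRAFT_102351 (scaffold 7, 1875215 to 1875457) had a mean of 168 ± 182 CPM (SD, n = 12, without TMM scaling) in the main libraries and TRAVEDRAFT_48895 (scaffold 7, 2216910 to 2219131) 144 ± 127 CPM (likewise), against a limit of 0.0189 CPM that 0 of the pooled preliminary counts allows. The adjacent genes MnP6s, MnP8s and MnP9s (scaffold 10, 2303472 to 2310731) had 3, 0 and 1 preliminary counts in all, against 57, 2437 and 179 main counts. Between groups of the main batch, no gene with at least 2 CPM in the 9 libraries of the other groups had 0 counts in the 3 libraries of any group, and 4 of 8252 had 1 to 3 counts in the AB libraries. In the preliminary batch 1 of 7650 genes with at least 2 CPM in both controls had 0 counts in the 3 AB libraries.

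Of 11 tested MnP genes 8 rose under FW and 3 were not called, and the test of the subfamily was lost with an estimated correlation (adjusted p = 0.111). Under AB 3 MnP genes fell while 5 rose, which reads shared between all copies would not give. Under FW shared reads stay open because no sequences were compared. A change of the whole region on scaffold 10 does not account for the rise of the 6 MnP genes tested there, since the median log2 fold change of the 22 other tested genes was 0.10. Whether the rise is a response to FW is a hypothesis, found and tested on the same libraries.

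Other groupings of the libraries were tested against each count. For each comparison of 3 with 3 libraries only 10 splits exist, too few for a share under 0.05. There the real split was 1 of 10 with as many genes, and the highest other counts were 0 for FW (4963), 1 for SD (2291), 0 for AB (6759), and 0 for FW against SD (2757), FW against AB (4564) and SD against AB (5871). Of 100 groupings of the 12 libraries, 1, the real one, gave as many genes shared by all 3 phases (1504, highest other 0), distinct to FW (542, highest other 0) and distinct to AB (3117, highest other 2223). The AB libraries lay far from all others, so a grouping that mixes them with others widens the spread within its groups. Few calls then follow in any case, and these groupings cannot decide whether chance gave the counts. For SD 2 of 100 gave at least 136 distinct genes, the other one 2377. The groupings behind 2377 and 2223 kept the 3 AB libraries together, which points to the structure of the samples, and the next highest counts were 0 and 187. For the number of gene lists called against control (2), 72 of 100 groupings gave as many (highest 5), and chance cannot be excluded.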

How the results depend on the processing

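All alternatives except thinning to equal depth were chosen before the data were examined. RLE size factors, no filter and the 10 CPM filter kept every count of genes within 1.5 times, as did DESeq2 except at 7 days and fits of the compared groups alone for the 6 comparisons at 3 days and the time difference, and the medians of all genes moved by at most 0.0329 (log2) with other scaling. With a 2-fold minimum the counts were 2220 (FW), 819 (SD), 3854 (AB), 1043 (FW against SD), 2231 (FW against AB), 3071 (SD against AB), 498 (all 3 phases) and 184, 35 and 1565 (distinct to FW, SD and AB), fewer by construction. Without 1 library they ranged from 4110 to 4869 (FW), 1361 to 2379 (SD), 6071 to 6586 (AB), 1865 to 2325 (FW against SD), 3722 to 4331 (FW against AB), 5132 to 5578 (SD against AB), 947 to 1620 (all 3), 361 to 568, 82 to 160 and 2616 to 3114 (distinct to FW, SD and AB), 0 to 689 (7 days) and 2527 to 3786 (time difference). The lowest values of SD, all 3 phases and distinct to SD came without control replicate 3, that of distinct to FW without FW replicate 1, and that at 7 days without control replicate 2, with 1 control left. Without 1 library the lists called over 8 comparisons numbered 4 (without control replicate 2) to 8, against 7, and with an estimated correlation 2. The cause of these shifts was not tested. At 7 days DESeq2 called 1343 genes, against 334, and the cause was not tested. The fit with the replicate block called 91 there, with fewer residual degrees of freedom and with AB replicate 3 taking no part in the comparison.

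The labels do not pair libraries by replicate number, but the deviations from the group means gave a hint of pairing among control, FW and SD. For replicates 1, 2 and 3 they correlated at 0.0705, 0.281 and 0.246 for FW and control (3 of 3 best with their own number). For SD and control the values were -0.0614, 0.394 and 0.178 (1 of 3), and for FW and SD -0.175, 0.281 and 0.215 (1 of 3). AB and control correlated at -0.136 to 0.0331 (1 of 3) and the 7-day libraries at -0.219 and -0.195. TvLac3 was highest in replicate 2 of the 3-day controls (216 CPM), FW (147 CPM) and SD (327 CPM). With the replicate block the counts were 4945, 2313 and 6681 for FW, SD and AB and 3101 for the time difference. Thinned to 15.5 M (1e6) counts, they were 4921, 2238, 6693 and 2969. Of 1369 alternative values for 102 results of named genes, 1287 kept direction and call, 82 kept the direction and lost the call, 68 of these without 1 library, and 0 reversed. At 7 days 0% of simulated 2-fold and 42% of 8-fold changes were recovered at the depth of those libraries, with few genes changed in the simulation.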

Other observations

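The tests of this part were set out before their results were seen, while the regions and genes named in it were chosen afterwards. Genes that changed at least 2-fold in 1 direction lay next to each other on the scaffolds. Under AB 12 adjoining tested genes on scaffold 7 (2237974 to 2276972, 39.0 kb, TRAVEDRAFT_126499 to TRAVEDRAFT_48911) all fell, with a median log2 fold change of -4.06, and 12 adjoining genes on scaffold 8 (2138146 to 2188991, 50.8 kb, TRAVEDRAFT_49706 to TRAVEDRAFT_49729) all rose, with a median of 3.32. On scaffold 9 (806405 to 820055) 7 adjoining genes rose under AB, with a median of 4.01, and 5 of them (811066 to 820055) also rose at least 2-fold under SD, with a median of 2.15. LDO1 lay in a run of 6 genes on scaffold 1 (604428 to 639016) that fell under AB with a median of -3.62. A run of 5 genes on scaffold 3 (1266641 to 1275196) fell under FW with a median of -1.80, and under AB the run from the same position held 6 genes (to 1278462), with a median of -2.68.

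Adjoining pairs that changed at least 2-fold in the same direction numbered 375 under FW, 68 under SD and 1034 under AB, where 1000 permuted gene orders within scaffolds gave means of 230, 33.1 and 692 and maxima of 280, 49 and 756 (permutation p = 0.001 for each, one-sided and the smallest that 1000 permutations can give). Under AB 33 runs of at least 5 genes were found, against at most 11 in permuted orders, while the 3 such runs under FW and the 1 under SD were matched by permuted orders. Reads that run from 1 gene model into the next would not give the excess at a distance, and 476 of the AB pairs lay at least 1 kb apart, against a permuted mean of 282 and maximum of 329. A candidate explanation is regulation by chromosomal neighbourhood, which stays a hypothesis, and local duplicates that share reads were not tested.

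HTP2 and HTP3, which adjoin each other on scaffold 12 (881424 to 882682 and 883884 to 884984) on the same strand, moved apart under SD by log2 fold changes of 0.67 and -0.84, and fell together under AB by -3.27 and -5.64. The HTP2 call under SD was lost without control replicate 1 or 3 or SD replicate 2 or 3 (adjusted p up to 0.139).

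The 3-day AB libraries may lie closer to the state of the 7-day controls than the other exposed libraries do. The fold changes of AB against SD at 3 days were correlated across genes with the difference between 7-day and 3-day controls, which share no library with them (Pearson 0.444 and Spearman 0.419 over 10838 genes, which are not independent replicates). Of the 5871 genes called between SD and AB, 71.0% had the same sign in the controls. Genes higher in both numbered 1317, against 771 for independent lists, and genes lower in both 1490, against 874, while 736 were opposite. For AB against FW the correlation was 0.373 and 66.7% had the same sign, with 896 genes higher in both (601 for independent lists), 1137 lower in both (677) and 707 opposite. The hypothesis that AB moves 3-day cultures towards the state of older cultures would fit these values, but the 7-day controls come from another batch, and a difference in batch or strain was not excluded.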
